A study of Homo sapiens with 60 samples.

How the data were processed

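RNA was sequenced from HepG2 cells after 24 h with vehicle or with 1 of 8 herbal extracts at 3 doses, in 60 libraries. Per the labels' protocols, RNA with an integrity number above 7 went into a directional MGIEasy library kit and was read on an MGIseq instrument as 100 bp pairs. Per the series text, the top dose of an extract was 500 µg/mL unless the concentration that reduced viability by 20% was lower, the other doses were 1/5 and 1/25 of it, and samples with little RNA were left out. The sample labels state 0.1% DMSO for the vehicle and the series text states 2%, a conflict the values do not settle. The series text also names wortmannin as a positive control, which is not analysed here.

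The deposited table holds expected counts for 60675 Ensembl gene identifiers in every library. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to hg38 with STAR 2.7.3a and summed per gene with RSEM 1.3.3, which shares out reads that fit several genes. The annotation release is not stated there. Of the deposited values 10.4% had a fraction, and all were rounded to whole counts before testing. Gene symbols came from a name table (56558 identifiers, 16698 of those tested) and positions from GENCODE 29 on GRCh38 (16812 of those tested).

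Library totals ran from 20.7 to 38.0 M expected counts (M, mega). Of 51 replicate pairs 0 were identical, and over genes with a mean of at least 50 counts the chi-square per degree of freedom between replicates ran from 2.70 to 65.1, so replicates spread more than counting alone would give. Because counts are compositional, levels are relative to the other genes of a library, and a change in total RNA per cell would not be seen.

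Groups, comparisons, gene lists, tests, the rule for named genes and most alternatives were fixed from the labels before the data were examined. The 19 groups with 2 or 3 libraries (54 libraries) were fitted together in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood negative binomial models with 1 mean per group, normalization by trimmed mean of M values and edgeR's filter by group, which left 16924 genes. P-values were adjusted by Benjamini and Hochberg within each comparison and called under 0.05. Each replicated extract was compared as high dose against low dose, and each dose against vehicle. Extracts within 1 code set were compared at the high dose. Standard errors come from the fitted coefficients. CPM in the text use the normalized library sizes.

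Of 30 pathway and 5 marker lists fixed in advance, 34 had at least 3 tested members and were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. A list is called raised or lowered when its adjusted p is under 0.05 in both high vs vehicle and high vs low, with 1 direction. Both comparisons use the same high-dose libraries, so they are not separate tests. Members are counted at an adjusted p over all genes and, beside it, adjusted over the list alone. Some genes are in more than 1 list, such as SLC7A11 among NRF2 and ATF4 targets, so list results are not all separate.

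Named genes follow a fixed rule. For each replicated extract they are the 8 largest and 8 smallest high vs vehicle changes among genes called in both high vs vehicle and high vs low with 1 sign, of at least 5 CPM in the higher group and not a clone name. Where fewer than 4 pass in a direction, all that pass are taken, then genes called in high vs vehicle alone, up to 4. Up to 4 members of each raised or lowered list with the smallest high vs low p are added, and 5 per direction for extract vs extract. CYP1A1, CYP3A4, HMOX1, HMGCS1 and ALB are always reported where tested, and CYP3A4 was not among the tested genes. The text names a part of the genes the rule gives. Genes outside it are said to have been chosen after their values were seen.

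Polygala and aucklandia have 1 library per dose and get no p-values. Their CPM, normalized over all 60 libraries, with 1 CPM added before taking log2, are described for genes of at least 10 CPM in vehicle or at the high dose whose level moved in 1 direction over the 3 doses. The 10 largest and 10 smallest changes are named. A list's median is placed among 10000 random lists matched on expression, and lists at or beyond percentile 1 or 99 in high vs low are named. Unlike lists of the replicated extracts, they did not also have to pass against vehicle.

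The fit was tested on simulated data made from these libraries. Simulated folds of 1.25, 1.5, 2 and 4 were recovered in 54, 66, 80 and 90% of genes between high and low yijin, with 4.65% of the calls false. With the 2 replicates of soshiho it was 20, 46, 80 and 90%, with 2.94% of the calls false. Beside the 1 list lowered by design, 1 other list was called in yijin and 2 in soshiho at the preset correlation. Libraries were simulated independently and without outlying ones, so these rates may not hold for the real libraries. Genes shared by the low doses were compared with 20 simulations of unchanged groups. Alternatives were other scalings (RLE and library size alone), no filter, DESeq2 1.42.0, a fit of only the compared groups, a block for the replicate number, other pseudocounts, and leaving out 1 library at a time. Where this leaves an arm with 1 library, that library is assumed to vary like the other groups. Correction of each library for gene length and GC content, leaving out the 2 libraries farthest from their replicates, and leaving out 1 library at a time for the gene lists, were chosen after seeing the data.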

Results

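Gene expression was measured by RNA sequencing in HepG2, a human hepatocellular carcinoma line that keeps part of the hepatocyte programme, after 24 h with herbal extracts or with the vehicle dimethyl sulfoxide (DMSO). The series title ties the extracts to decoctions and single herbs linked with Qi, a concept of traditional East Asian medicine, and the design asks how each extract changes the transcriptome at falling doses. Hot-water extracts of 2 multi-herb decoctions, Yijin-tang (here yijin) and Soshiho-tang (soshiho), were tested. Extracts in 70% ethanol were made from Liriope or Ophiopogon tuber (liriope), Schisandra fruit (schisandra), longan aril (longan), Zizyphus seed (zizyphus), Polygala root (polygala) and Aucklandia root (aucklandia). High, medium and low doses were 500, 100 and 20 µg/mL, except for polygala (250, 50 and 10 µg/mL) and aucklandia (280, 56 and 11.2 µg/mL), whose top dose was set by a toxicity limit per the series text. The 60 libraries held 3 of vehicle, 3 per dose of yijin, liriope, schisandra, longan and zizyphus, 2 per dose of soshiho, and 1 per dose of polygala and aucklandia. Library totals ran from 20.7 to 38.0 M expected counts (M, mega). The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The vehicle libraries carry a sample code of their own, shared with no treated library, while all doses of an extract share a code, so high vs low dose was read first and vehicle beside it. Levels are CPM (counts scaled to a common library total, mean ± SD), and log2 changes are high vs low dose ± SE unless another comparison is named.

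In cells given the high dose of yijin, CYP1A1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor (AhR), rose from 7.51 ± 0.559 CPM at the low dose to 72.6 ± 1.33 CPM (n = 3 each). This was a 9.64-fold change (log2 3.27 ± 0.072, adjusted p = 2.9e-33), and vehicle had 7.95 ± 0.390 CPM. AKR1B10, an aldo-keto reductase gene, rose from 46.7 ± 2.92 to 119 ± 4.56 CPM (log2 1.36 ± 0.055, adjusted p = 9.0e-23). Genes for metallothioneins, small cysteine-rich proteins that bind zinc and copper, fell together. MT1G went from 57.7 ± 2.51 to 12.6 ± 0.412 CPM (log2 -2.20 ± 0.23, adjusted p = 3.3e-09). MT1F, MT1E, MT1X and MT2A changed by -2.34, -1.58, -1.51 and -1.40 on the log2 scale. Metallothionein genes are close copies of each other, so here and below their reads could be split between copies. HMGCS1, an early enzyme of cholesterol synthesis, fell from 399 to 267 CPM (log2 -0.58 ± 0.056, adjusted p = 2.6e-10). CYP1A1 lies on chromosome 15 at 74719542 to 74725610 (GRCh38), and MT1G and MT1F lie in the metallothionein cluster of chromosome 16 at 56666731 to 56668065 and 56657694 to 56660698.

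Further genes that rose with yijin were SLC39A10, a zinc importer (log2 0.96 ± 0.082), AQP3, a water and glycerol channel (0.93 ± 0.12), PLAC8 (0.77 ± 0.12) and ZC3H12D (0.56 ± 0.10). IGFBP1, a secreted binding protein for insulin-like growth factors, rose from 53.3 ± 4.02 to 104 ± 8.55 CPM (0.97 ± 0.26, adjusted p = 0.0122). The IGFBP1 call was lost without replicate 1 of the low dose or replicate 2 of the high dose, each with an adjusted p of 0.0566. HAMP, the iron-regulating hormone hepcidin (log2 -1.09 ± 0.18), KNG1, kininogen (-1.08 ± 0.13), and TRIM50 (-0.92 ± 0.075) fell. HMOX1, the haem oxygenase gene, was at 56.7 and 53.8 CPM in low and high dose (adjusted p = 0.55), and ALB, albumin, was at log2 -0.12 (adjusted p = 0.30). Neither passed the test.

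By group, 17 of 23 NRF2 targets, which serve oxidative and electrophile defence, rose with yijin and 1 fell (18 and 1 adjusted over the list alone; median log2 0.32, adjusted p = 1.0e-51). NQO1, a quinone reductase, went from 431 to 656 CPM (log2 0.61 ± 0.048), the exporter ABCC2 changed by 0.54 and the aldo-keto reductase AKR1C1 by 0.52. Of 8 AhR targets 3 rose and 0 fell, also adjusted over the list alone (median 0.66, adjusted p = 3.2e-28), NQO1 being in both lists. Cholesterol synthesis fell in 21 of 24 genes (23 adjusted over the list alone; median -0.38, adjusted p = 1.1e-63), including LSS (-0.58), TM7SF2 (-0.55) and ACAT2 (-0.49). Fatty acid synthesis fell in 10 of 14 genes (12 adjusted over the list alone; median -0.34, adjusted p = 1.2e-35). ACSS2, an acetyl-CoA synthetase, fell from 152 ± 4.33 to 83.2 ± 0.616 CPM (-0.87 ± 0.041, adjusted p = 2.7e-20), and the desaturase FADS2 by log2 0.57. Of 9 genes in the metal response list 8 fell (8 adjusted over the list alone; median -1.51, adjusted p = 7.6e-21), while the zinc importer SLC39A10 rose. Of 15 acute phase genes 12 fell (12 adjusted over the list alone; median -0.30, adjusted p = 7.6e-21), including the haem carrier HPX (-0.86) and haptoglobin, HP (-0.42). Those 6 lists were also past 0.05 with an estimated correlation between genes.

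Yijin also raised 12 of 29 hypoxia and glycolysis genes (13 adjusted over the list alone; median 0.22, adjusted p = 1.9e-11, and adjusted p = 0.0618 with an estimated correlation), among them the glucose transporter SLC2A1 (0.32 ± 0.044) and lactate dehydrogenase, LDHA (0.37 ± 0.060). Of 21 immediate early and MAPK feedback genes 8 rose (8 adjusted over the list alone; median 0.12, adjusted p = 7.2e-07), with DUSP6 at 0.51 ± 0.064 and EGR1 at 0.52 ± 0.087. Against vehicle the list had an adjusted p of 0.102 with an estimated correlation. Of 13 Wnt targets 3 fell (3 adjusted over the list alone; median -0.13, adjusted p = 0.035, and adjusted p = 0.123 with an estimated correlation). The Wnt call was also lost after the length and GC correction (0.0594) and, against vehicle, with library size alone (0.069997). It was lost without replicate 3 of the high dose (0.0954), where 0 members were called (NKD1, GLUL and NOTUM at an adjusted p of 0.0507, 0.0733 and 0.0790), and without replicate 2 of the low dose (0.0904, 1 member). Without replicate 3 of the low dose 1 member was called. Over all 16924 tested genes, edgeR called 1318 between high and low yijin, 640 higher and 678 lower, of which 27 and 41 differed by at least 2-fold. The count was 836 without replicate 2 of the high dose. With library size alone as the scaling, 35.9% of calls were higher, against 48.6% here.

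**Figure D1:**
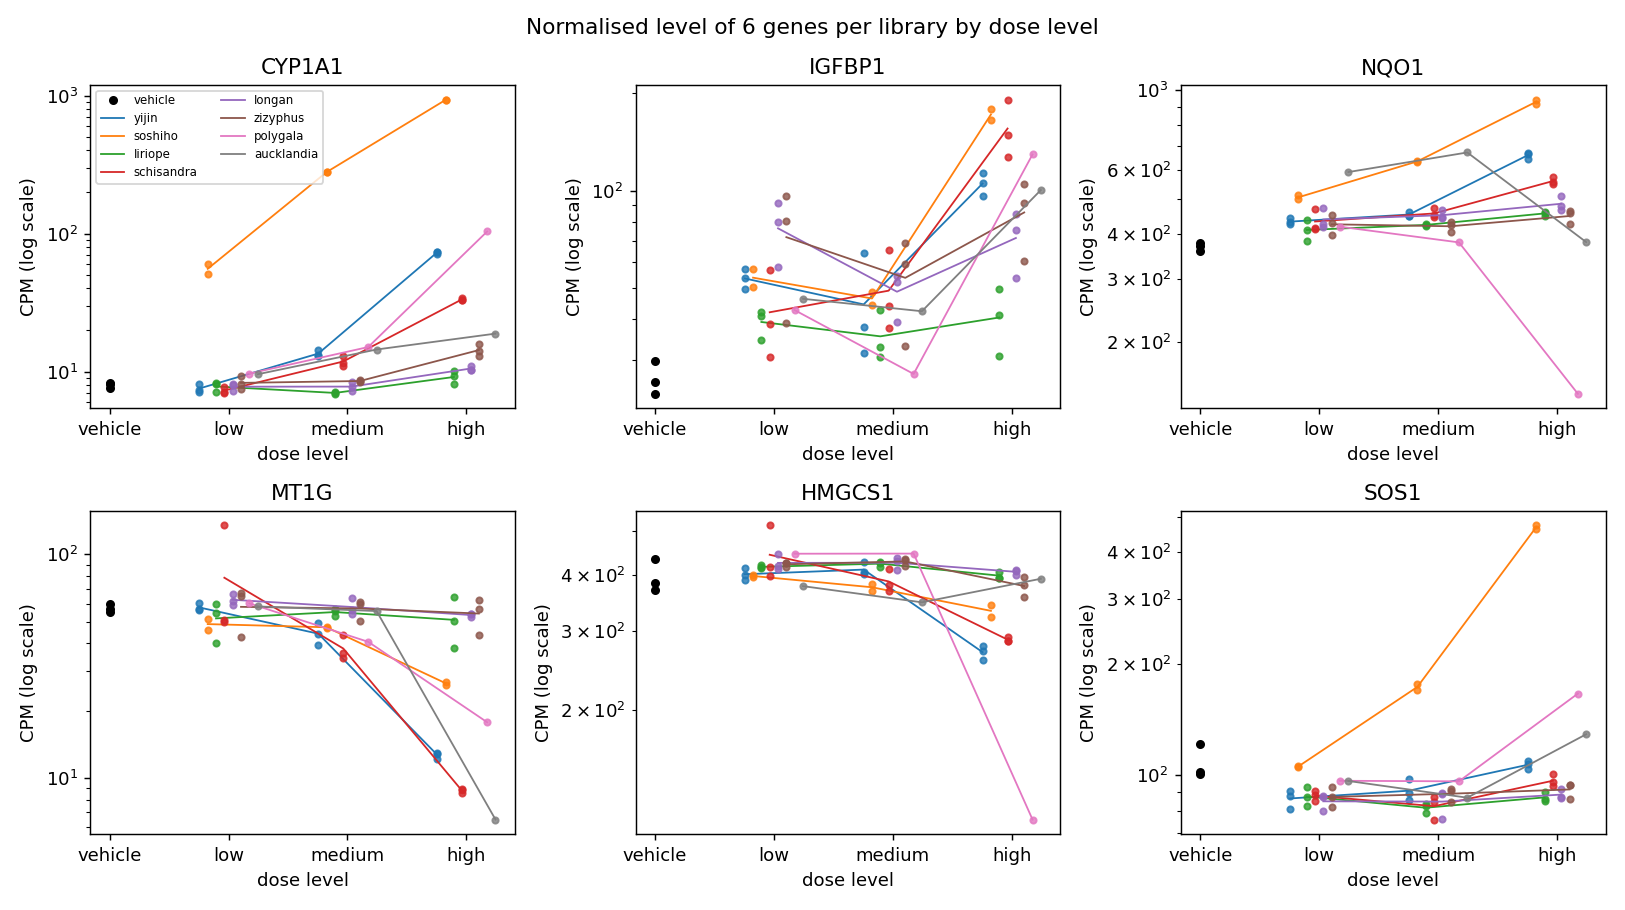
CPM of 6 genes by extract and dose on log axes, 1 point per library, with lines through the dose means. The scaling here is over all 60 libraries, so values differ slightly from those of the text for replicated extracts. CYP1A1 was at 926 and 934 CPM at the high dose of soshiho, 71.6 to 74.1 CPM with yijin and 7.57 to 8.31 CPM in vehicle, and SOS1 at 473 and 463 CPM with soshiho.

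Soshiho gave the highest CYP1A1 level of the replicated extracts: 55.4 ± 6.11 CPM at the low, 278 ± 2.34 at the medium and 924 ± 5.16 at the high dose (n = 2 each). The high vs low change was 4.06 ± 0.075 (adjusted p = 1.9e-36), and 6.86 against vehicle. AHRR, a repressor of the aryl hydrocarbon receptor and itself one of its targets, rose from 0.985 ± 0.154 to 6.16 ± 0.348 CPM (log2 2.65 ± 0.28, adjusted p = 1.5e-09). SOS1, an exchange factor that activates RAS, rose from 105 ± 0.650 to 465 ± 7.14 CPM, by 4.41-fold (log2 2.14 ± 0.077, adjusted p = 8.8e-25), through 173 ± 4.23 CPM at the medium dose. SOS1-IT1, a transcript inside a SOS1 intron, went from 1.69 to 5.99 CPM (1.82 ± 0.24, adjusted p = 5.7e-07). SOS1 lies on chromosome 2 at 38981396 to 39124345 and SOS1-IT1 at 38992279 to 38993857 on the same strand, so reads of unspliced SOS1 could be assigned to either.

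LRRC25 (log2 2.52 ± 0.27), AQP3 (1.77 ± 0.14), IGFBP1 (1.67 ± 0.32) and the glycosyltransferase GALNT6 (1.59 ± 0.16) also rose with soshiho. Genes that fell were the homeobox gene HOXD1, from 13.3 ± 0.133 to 5.61 ± 0.771 CPM (log2 -1.24 ± 0.13, adjusted p = 2.3e-09), HAMP (-1.34 ± 0.22), KNG1 (-1.16 ± 0.16), the potassium channel KCNJ10 (-1.01 ± 0.10) and the betaine transporter SLC6A12 (-0.98 ± 0.14). CEBPA, a transcription factor of hepatocyte differentiation, fell from 161 ± 2.73 to 95.5 ± 2.56 CPM (-0.75 ± 0.079, adjusted p = 1.9e-09). HMOX1 rose from 59.8 ± 2.74 to 93.4 ± 0.472 CPM (0.64 ± 0.069, adjusted p = 3.4e-09), and ALB was at -0.17 (adjusted p = 0.23), which did not pass. HMGCS1 went from 396 ± 1.98 to 330 ± 14.9 CPM (-0.26 ± 0.069, adjusted p = 0.0120), a call lost without replicate 3 of the high dose (0.227, and 0.0823 against vehicle) or 2 or 3 of the low dose (0.0792 and 0.0997).

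In soshiho 18 of 23 NRF2 targets rose (22 adjusted over the list alone; median log2 0.60, adjusted p = 3.7e-89), with NQO1 from 503 to 922 CPM (0.87 ± 0.059), OSGIN1 at 0.94 and the sulfiredoxin SRXN1 at 0.80. Of 8 AhR targets 7 rose (7 adjusted over the list alone; median 2.19, adjusted p = 3.7e-89). ATF4 targets, of the amino acid and integrated stress response, rose in 9 of 28 genes (13 adjusted over the list alone; median 0.17, adjusted p = 1.4e-08), with the cystine transporter SLC7A11 at 0.79 and STC2 at 0.39. Mitosis genes fell in 12 of 28 (20 adjusted over the list alone; median -0.23, adjusted p = 4.1e-15), with the spindle factor TPX2 going from 289 to 231 CPM (-0.33 ± 0.050) and KIF20A changed by -0.38. Fatty acid synthesis fell in 5 of 14 genes (5 adjusted over the list alone; median -0.14, adjusted p = 1.0e-06), with GPAM, a glycerol-phosphate acyltransferase, at -0.53 and the transcription factor SREBF1 at -0.43. Those 5 lists were also past 0.05 with an estimated correlation, and with any 1 library left out at the preset one. The members called were fewer without replicate 2 of the high dose (4 ATF4 targets, 5 mitosis genes) and without replicate 3 of the low dose (5 and 6). Fatty acid synthesis had 3 without replicate 3 of the high dose or 2 or 3 of the low dose.

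The other 8 lists that moved with soshiho passed in both comparisons only at the preset correlation. With an estimated correlation LXR targets passed against the low dose alone (adjusted p = 0.0420) and PPARA targets against vehicle alone (0.0138). Hypoxia and glycolysis genes rose in 3 of 29 (5 adjusted over the list alone; median 0.15; adjusted p = 0.267 with an estimated correlation), with SLC2A1 from 649 to 951 CPM (0.55 ± 0.055). Immediate early genes rose in 5 of 21 (5 adjusted over the list alone; median 0.12; adjusted p = 0.0802 with an estimated correlation), with DUSP6 at 0.81. PPARA targets of fatty acid oxidation rose in 5 of 17 (6 higher and 2 lower adjusted over the list alone; median 0.10; adjusted p = 0.0906 with an estimated correlation), with CPT1A at 0.57. Immediate early members called were 3 without replicate 2 of the high dose or 2 or 3 of the low dose, and PPARA members 3 without replicate 3 of the low dose. Against vehicle the immediate early list did not pass without replicate 1 or 3 of vehicle (adjusted p = 0.0503 and 0.0584) or 2 of the high dose (0.0640).

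Among lists lowered by soshiho, the metal response had 5 of 9 genes lower and 1 higher (6 and 1 adjusted over the list alone; median -0.67; adjusted p = 0.175 with an estimated correlation). Of the 5, 0 were called without replicate 3 of the high dose (MT1G, MT1M, MT1X, MT1F and SLC30A1 at an adjusted p of 0.241, 0.267, 0.0962, 0.107 and 0.177) or 2 of the low dose, 1 without 2 of the high dose and 3 without 3 of the low dose. Against vehicle the list did not pass without replicate 3 of the high dose (0.0689). Acute phase genes had 4 of 15 lower (7 adjusted over the list alone; median -0.17; adjusted p = 0.0899 with an estimated correlation), and 2 without replicate 2 or 3 of the high dose. Hepatocyte genes had 3 of 27 lower and 1 higher (4 and 1 adjusted over the list alone; median -0.06; adjusted p = 0.281 with an estimated correlation). Against vehicle that list did not pass without replicate 3 of vehicle (0.0570) or 2 of the high dose (0.0723). LXR targets of sterol export were lower in 3 of 9 (4 adjusted over the list alone; median -0.11; adjusted p = 0.0905 against vehicle with an estimated correlation). Without any 1 of the 4 libraries MYLIP (0.109 to 0.294) and ABCG8 (0.0575 to 0.452) were not called, which left 1 member. The LXR list did not pass without replicate 2 of the low dose (0.0613) or, against vehicle, without replicate 3 of the high dose (0.0807) or 2 of vehicle (0.0665). Of 3 fibroblast markers, a list fixed to look for other cell types, 1 was lower (2 adjusted over the list alone; median -0.46; adjusted p = 0.0802 with an estimated correlation). The member, COL1A1, lost its call without any 1 library (0.133 to 0.344). The list did not pass without replicate 3 of the high dose (0.237, and 0.114 against vehicle) or 3 of the low dose (0.0665). It was also lost without the filter (adjusted p = 0.0561), after the length and GC correction (0.0527) and without the 2 outlying libraries (0.0632). The LXR and hepatocyte lists did not pass against vehicle with library size alone (0.0724 and 0.0722).

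In total edgeR called 860 genes between high and low soshiho, 476 higher and 384 lower, with 53 and 20 at least 2-fold apart. The count was 490 and 494 without replicate 2 or 3 of the high dose, 501 and 467 without replicate 2 or 3 of the low dose, and 1707 when only these 4 libraries were fitted. With library size alone as the scaling 44.1% of calls were higher, against 55.3% here.

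At the high dose of schisandra, metallothionein genes fell furthest. MT1G was at 8.70 ± 0.186 CPM against 77.9 ± 47.8 at the low dose and 56.9 ± 2.33 in vehicle (log2 -3.18 ± 0.24, adjusted p = 4.3e-13). MT1F, MT1E, MT1X and MT2A changed by -3.03, -2.59, -2.39 and -1.99. Without replicate 1 of the low dose the MT1G change was -2.53 and that of MT1E -1.997, and both calls held. SLC30A1, the gene of the zinc exporter of the plasma membrane, fell from 109 to 63.9 CPM (-0.77 ± 0.060, adjusted p = 6.1e-13). CYP1A1 rose from 7.23 ± 0.355 to 33.3 ± 0.763 CPM (2.20 ± 0.073, adjusted p = 7.8e-26), n = 3 each. IGFBP1 rose from 41.7 ± 13.4 to 155 ± 32.5 CPM (1.89 ± 0.26, adjusted p = 1.4e-06). RNASET2, a secreted ribonuclease (1.03 ± 0.098), AKR1B10 (0.98 ± 0.055), PLAC8 (0.90 ± 0.12), DDIT4, an inhibitor of mTOR signalling (0.77 ± 0.10), and HMOX1 (0.33 ± 0.057) rose as well. LOX, a lysyl oxidase, was at 0.90 ± 0.22 (adjusted p = 0.0053), a call lost without replicate 3 of the high dose (adjusted p = 0.0592). The low-dose spread of the metallothioneins came with library 1 of that group, which stood apart from its replicates (SD of log2 differences 0.243, against 0.0693 to 0.162 in 52 other libraries).

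In schisandra 17 of 23 NRF2 targets rose and 1 fell (20 and 1 adjusted over the list alone; median log2 0.33, adjusted p = 1.9e-40), including ABCC2 (0.50), SRXN1 (0.45) and OSGIN1 (0.60). Of 8 AhR targets 2 rose (6 higher and 1 lower adjusted over the list alone; median 0.61, adjusted p = 1.2e-17). Hypoxia and glycolysis genes rose in 23 of 29 (23 adjusted over the list alone; median 0.31, adjusted p = 2.2e-30), with aldolase, ALDOA, at 0.58 ± 0.059, SLC2A1 at 0.40 and GPI at 0.39. ATF4 targets rose in 10 of 28 and fell in 1 (12 and 1 adjusted over the list alone; median 0.13, adjusted p = 6.1e-08), with SLC7A11 at 0.53. Lysosome and autophagy genes rose in 3 of 27 (3 adjusted over the list alone; median 0.08, adjusted p = 3.9e-04). The autophagy receptor SQSTM1 went from 210 ± 1.62 to 308 ± 3.16 CPM (0.55 ± 0.038). Cholesterol synthesis fell in 20 of 24 genes (20 adjusted over the list alone; median -0.30, adjusted p = 1.5e-41). HMGCS1 went from 439 to 285 CPM (-0.62 ± 0.056) and SQLE changed by -0.43. Fatty acid synthesis fell in 10 of 14 (11 adjusted over the list alone; median -0.20, adjusted p = 5.9e-19), with ACSS2 at -0.52 and GPAM at -0.46. In the metal response list 8 of 9 genes fell and SLC39A10 rose (8 and 1 adjusted over the list alone; median -2.39, adjusted p = 1.8e-45). Acute phase genes fell in 7 of 15 (9 lower and 1 higher adjusted over the list alone; median -0.26, adjusted p = 1.4e-12), with HPX at -0.77 and HP at -0.53. Mitosis genes fell in 11 of 28 (23 adjusted over the list alone; median -0.18, adjusted p = 2.7e-13). Those 10 lists held with an estimated correlation, and with any 1 library left out at the preset one. The mitosis members called were 4 without replicate 1 of the low dose and 17 without replicate 3 of the low dose, where 4 AhR targets were higher. ATF4 targets had 6 higher without replicate 3 of the high dose.

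Immediate early genes rose in 10 of 21 with schisandra (12 adjusted over the list alone; median 0.24, adjusted p = 1.4e-09), with IER3 at 0.66 and JUN at 0.54. Without replicate 1 of the low dose 6 rose. Against vehicle the adjusted p was 0.0801 with an estimated correlation. Heat shock genes fell in 7 of 18 (10 lower and 1 higher adjusted over the list alone; median -0.12; adjusted p = 0.0766 with an estimated correlation), in 2 without replicate 1 or 3 of the high dose, and in 3 without replicate 1 of the low dose. Wnt targets fell in 4 of 13 (4 adjusted over the list alone; median -0.05; adjusted p = 0.0672 with an estimated correlation), with the Wnt antagonist DKK1 at -0.69 ± 0.083. Only 2 were called without any library but replicate 1 of the low dose, and the list did not pass without replicate 2 of the high dose (0.0639) or 3 of the low dose (0.0945). ALB was at -0.04 (adjusted p = 0.80) and did not pass. Over all genes, edgeR called 1240 between high and low schisandra, 664 higher and 576 lower, with 28 and 17 at least 2-fold apart. The count was 615 without replicate 1 of the low dose, 731 without that library and replicate 2 of high liriope, the 2 libraries farthest from their replicates, and 132 when only the 6 libraries were fitted. With library size alone as the scaling 29.1% of calls were higher, against 53.5% here.

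Liriope, longan and zizyphus had 5, 3 and 6 genes called between low and high dose with the expression filter, and 207, 63 and 79 without it. With liriope, AKR1C1 and AKR1C2, aldo-keto reductases of steroid and aldehyde metabolism with near-identical sequences, rose. AKR1C1 went from 540 ± 24.6 to 713 ± 27.7 CPM (log2 0.40 ± 0.050, adjusted p = 1.0e-05) and AKR1C2 from 212 ± 22.8 to 292 ± 26.6 CPM (0.46 ± 0.061, adjusted p = 2.4e-05). With zizyphus, CYP1A1 rose from 8.25 ± 0.947 to 14.2 ± 1.39 CPM (0.79 ± 0.080, adjusted p = 2.6e-08). ASNS, asparagine synthetase, fell from 32.4 to 24.0 CPM (-0.43 ± 0.053, adjusted p = 3.0e-06) and SLC13A3, a dicarboxylate transporter, from 78.9 to 63.4 CPM (-0.32 ± 0.047, adjusted p = 2.3e-04). With longan, HMOX1 rose from 58.0 ± 1.36 to 72.8 ± 2.50 CPM (0.33 ± 0.057, adjusted p = 0.012), and CYP1A1 (0.44 ± 0.082) and AKR1C2 (0.33 ± 0.061) were each at an adjusted p of 0.020. In liriope, CYP1A1, HMOX1, HMGCS1 and ALB were at 0.23, 0.13, -0.06 and 0.17, and none passed. HMGCS1 and ALB were at -0.07 and -0.06 in longan and at -0.16 and -0.03 in zizyphus, and HMOX1 was at 0.12 in zizyphus, without passing.

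The longan calls were fragile. HMOX1 was lost without replicate 1 or 2 of the high dose (adjusted p = 0.118 and 0.121) or 2 or 3 of the low dose (0.230 and 0.101). AKR1C2 was lost without any library but replicate 1 of the low dose (0.0821 to 0.427), and CYP1A1 without any 1 of the 6 libraries (0.0821 to 0.476). In liriope the adhesion molecule ICAM1 (-0.28 ± 0.052, adjusted p = 0.018) was lost without replicates 1 or 3 of the high dose (0.0847 and 0.0778) or 2 or 3 of the low dose (0.264 and 0.166). AKR1B10 in liriope (0.28 ± 0.056, adjusted p = 0.044) was lost without replicates 1 or 2 of the high dose (0.0619 and 0.696) or 2 or 3 of the low dose (0.318 and 0.639). In zizyphus TIMP3, a metalloproteinase inhibitor (0.19 ± 0.034, adjusted p = 0.0059), was lost without replicates 2 or 3 of the high dose (0.0969 and 0.0602) or 3 of the low dose (0.117). The sodium channel subunit SCNN1A (-0.43 ± 0.075, adjusted p = 0.0045) was lost without replicates 2 or 3 of the high dose (0.0539 and 0.128) or 1 of the low dose (0.0825). The SLC13A3 call against vehicle in zizyphus was lost without replicate 2 or 3 of vehicle (0.0944 and 0.114) or 2 or 3 of the high dose (0.0910 and 0.0775).

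EdgeR called 5 genes in liriope (3 higher, 2 lower), 3 in longan (all higher, 0 lower) and 6 in zizyphus (3 and 3) between high and low dose. At an unadjusted p under 0.05 there were 1360, 395 and 787 genes, and DESeq2 called 14, 6 and 13. A fit of only the 2 groups called 0 genes in liriope and 0 in zizyphus, where the adjusted p was 0.957 for AKR1C1 in liriope and 0.281 for both CYP1A1 and ASNS in zizyphus, and 0.525 for SLC13A3. In liriope the count was 2 without replicate 2 or 3 of the low dose. In longan it was 0 without replicate 1 or 2 of the high dose or 2 or 3 of the low dose and 1 without replicate 3 of the high dose, and in zizyphus 3 without replicate 2 or 3 of the high dose. With library size alone as the scaling 28.6% of the liriope calls were higher, against 60% here.

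As a group, NRF2 targets were raised in all 3 of these extracts. In liriope 3 of 23 rose (6 adjusted over the list alone; median log2 0.12, adjusted p = 7.7e-13). In longan 2 rose (9 adjusted over the list alone; median 0.12, adjusted p = 1.3e-33), 0 without replicate 1 or 2 of the high dose or 2 or 3 of the low dose, and 1 without replicate 3 of the high dose. In zizyphus 0 rose (5 higher and 1 lower adjusted over the list alone; median 0.06, adjusted p = 4.1e-05, and adjusted p = 0.0691 with an estimated correlation). With liriope, cytoskeleton genes were lower as a list with 0 of 20 members called (6 lower adjusted over the list alone; median -0.07, adjusted p = 1.7e-05), a call kept with an estimated correlation. NF-kB and inflammatory genes had 1 of 11 lower, ICAM1 (2 adjusted over the list alone; median -0.21; adjusted p = 0.05002 against vehicle with an estimated correlation). The count was 0 without replicate 1 or 3 of the high dose or 2 or 3 of the low dose, and 2 without replicate 2 of the high dose. Immediate early genes had 0 of 21 (1 lower adjusted over the list alone; median -0.09; adjusted p = 0.0658 with an estimated correlation). Higher with liriope were lists with 0 members called, and with the median, the count adjusted over the list alone and the adjusted p with an estimated correlation as follows: PPARA targets 0.09, 1 and 0.0893, S phase genes 0.04, 0 and 0.190, hypoxia genes 0.09, 0 (1 lower) and 0.432, cytosolic ribosomal proteins 0.12, 0 and 0.432, and nuclear-encoded oxidative phosphorylation 0.09, 0 and 0.432. Replicate 2 of high liriope stood apart from its replicates (SD of log2 differences 0.215), and without it and replicate 1 of low schisandra the ribosomal list turned lower, while S phase (against vehicle, adjusted p = 0.0569), hypoxia (0.0886) and oxidative phosphorylation (0.305) did not pass. S phase did not pass against the low dose with library size alone (0.202). Without replicate 2 of high liriope alone the ribosomal list turned lower (0.456, and 0.844 against vehicle), and hypoxia (0.0774), oxidative phosphorylation (0.3485) and, against vehicle, S phase (0.09705) did not pass. Without replicate 3 of low liriope ribosomal (0.616), oxidative phosphorylation (0.318) and S phase genes (0.0526) did not pass. PPARA targets (0.0606) and hypoxia genes (0.149) did not pass without replicate 3 of the high dose, hypoxia without replicate 1 of the low dose (0.0695), and S phase against vehicle without replicate 3 of vehicle (0.0872).

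In zizyphus AhR targets were higher, with CYP1A1 the 1 of 8 called (2 adjusted over the list alone; median 0.07; adjusted p = 0.0525 against vehicle with an estimated correlation). Hypoxia genes had 0 of 29 called (7 higher adjusted over the list alone; median 0.15; adjusted p = 0.0585 with an estimated correlation). Fatty acid synthesis had 0 of 14 (4 lower adjusted over the list alone; median -0.08; adjusted p = 0.358 against vehicle with an estimated correlation, and 0.527 with library size alone). Against vehicle the last list did not pass without replicate 2 of vehicle (0.0970) or 2 of the high dose (0.121).

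**Figure D2:**
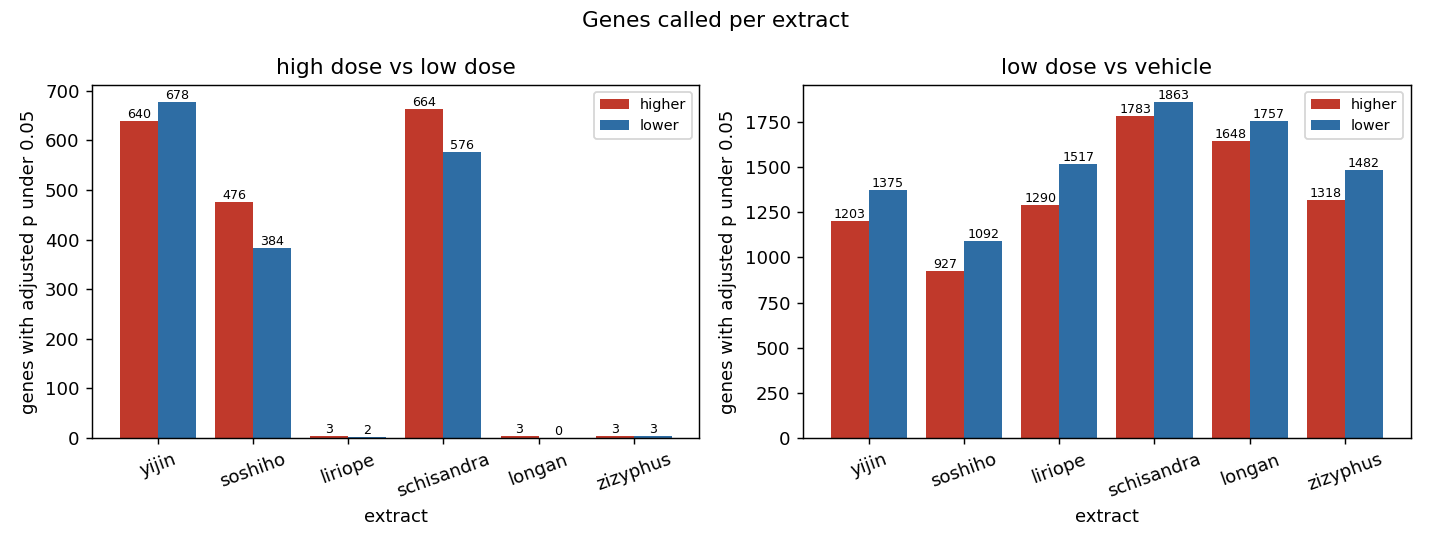
Number of genes called by edgeR at an adjusted p under 0.05, higher (red) and lower (blue), for each replicated extract, between high and low dose (left) and between low dose and vehicle (right). Between high and low dose yijin had 1318, soshiho 860 and schisandra 1240 calls, and liriope, longan and zizyphus 5, 3 and 6.

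Extracts that share a library code were compared with each other at the same high dose. Yijin and soshiho differed most in CYP1A1, at 72.6 ± 1.33 and 924 ± 5.16 CPM (yijin minus soshiho, log2 -3.67 ± 0.062, adjusted p = 6.4e-38). AHRR (-2.74 ± 0.24), LRRC25 (-2.37 ± 0.23), SOS1 at 106 ± 2.47 and 465 ± 7.14 CPM (-2.13 ± 0.067, adjusted p = 4.2e-27) and SOS1-IT1 (-1.82 ± 0.22) were lower with yijin too. HOXD1 (1.20 ± 0.12), CRYAA (1.19 ± 0.30), KCNJ10 (0.98 ± 0.095), PDGFRB (0.90 ± 0.14) and EGR1 (0.69 ± 0.10) were higher with yijin. The CRYAA call was lost without replicate 2 or 3 of soshiho (adjusted p = 0.183 and 0.127) or 3 of yijin (0.0653). As lists, AhR targets (7 of 8 lower in yijin, median -2.26), NRF2 targets (15 of 23, -0.22), cholesterol synthesis (15 of 24, -0.25) and ATF4 targets (14 of 28, -0.25) were lower with yijin. Mitosis genes (10 of 28, 0.18) and endoplasmic reticulum chaperones (4 of 20, 0.11) were higher, as was the list of 3 fibroblast markers with 1 member called. The metal response (4 of 9, median -0.78), fatty acid synthesis (3 of 14, -0.13), PPARA targets (3 of 17, -0.08) and p53 targets (5 of 22, -0.07) were lower with yijin. All were past 0.05 with an estimated correlation too. Without replicate 2 of soshiho fewer members were called: cholesterol synthesis 7, ATF4 targets 5, mitosis 3, chaperones 1 and metal response 1. Without replicate 3 of soshiho it was NRF2 targets 9, mitosis 6, p53 targets 3, metal response 2 and chaperones 1, and the fibroblast list did not pass (adjusted p = 0.196). Without any 1 yijin library the metal response had 2, and without replicate 2 of yijin chaperones had 2. EdgeR called 598 genes, 222 higher and 376 lower in yijin. The count was 267 and 292 without replicate 2 or 3 of high soshiho and 1255 when only the 5 libraries were fitted.

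Liriope and schisandra at 500 µg/mL differed in MT1F (liriope minus schisandra, 2.57 ± 0.20), MT1G at 50.7 ± 13.3 and 8.70 ± 0.186 CPM (2.55 ± 0.25, adjusted p = 2.7e-10), MT1X (2.03 ± 0.18), MT1E (2.002 ± 0.22) and MT2A (1.41 ± 0.20), all higher with liriope. IGFBP1 (-1.93 ± 0.26), CYP1A1 (-1.88 ± 0.071), TMCC1 (-1.24 ± 0.088) and the stress cytokine GDF15, at 82.7 ± 9.24 and 185 ± 10.7 CPM (-1.16 ± 0.084, adjusted p = 6.1e-14), were higher with schisandra. Cholesterol synthesis (19 of 24 genes, median 0.31), mitosis (20 of 28, 0.24) and the metal response (8 of 9 higher and 1 lower) were higher with liriope. Hypoxia genes (17 of 29, -0.26), NRF2 targets (11 of 23 lower and 1 higher, -0.20), NF-kB genes (7 of 11, -0.33) and immediate early genes (11 of 21, -0.24) were lower, as were the 5 immune cell markers with 1 member called. Fatty acid synthesis (6 of 14, 0.19), heat shock genes (8 of 18, 0.14) and acute phase genes (6 of 15 higher and 1 lower, 0.19) were higher with liriope. ATF4 targets (13 of 28, -0.17), AhR targets (2 of 8, -0.33), gluconeogenesis genes (3 of 14, -0.18) and lysosome genes (4 of 27 lower and 2 higher, -0.09) were lower. All were also past 0.05 with an estimated correlation. Without replicate 2 of liriope 10 fatty acid synthesis and 13 mitosis genes were higher and 7 lysosome genes lower, and 2 immune markers were called. Without replicate 3 of schisandra 5 heat shock and 10 hypoxia genes were called, and without replicate 1 of schisandra or 3 of liriope 7 immediate early genes. The immune markers did not pass without replicate 1 of liriope or of schisandra (adjusted p = 0.0674 and 0.0535). EdgeR called 1220 genes (594 higher, 626 lower), 805 without replicate 3 of high schisandra and 245 when only the 6 libraries were fitted. Longan and zizyphus differed in 9 genes, 6 higher in longan and 3 lower, with 768 at an unadjusted p under 0.05. S100P (0.55 ± 0.11), ASNS at 34.6 and 24.0 CPM (0.53 ± 0.053, adjusted p = 2.1e-08), SCNN1A (0.46 ± 0.075), SLC7A11 (0.43 ± 0.084) and HMOX1 (0.28 ± 0.057) were higher in longan. CYP1A1 (-0.44 ± 0.077), NEDD9 (-0.30 ± 0.051) and TIMP3 (-0.19 ± 0.034) were lower. Of these 8 genes only ASNS kept its call without any 1 library and in a fit of only these 6 libraries. S100P had an adjusted p up to 0.696, HMOX1 0.643, SLC7A11 0.274, CYP1A1 0.162, NEDD9 0.0769, TIMP3 0.0706 and SCNN1A 0.0686 with 1 library left out. The count was 4 without replicate 1 or 2 of longan or 1 or 3 of zizyphus. Lists higher in longan with an estimated correlation were ATF4 targets (2 of 28 members called, median 0.10, adjusted p = 3.6e-05), cholesterol synthesis (0 of 24, 0.08, 0.00355), NRF2 targets (2 of 23, 0.07, 0.00976) and lysosome genes (1 of 27, 0.04, 0.0169). SLC7A11 is a called member of both the ATF4 and the NRF2 list. With 1 library left out, NRF2 targets had 0 or 1 members called in all 6 fits, ATF4 targets 1 in 5 of them, and lysosome genes 0 without replicate 1 or 2 of longan or 1 or 3 of zizyphus. Lysosome genes did not pass without replicate 3 of zizyphus (0.0620).

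Yijin, soshiho and schisandra shared many high vs low calls. Their common calls numbered 133 higher and 97 lower genes, among them CYP1A1, IGFBP1, AKR1B10, NQO1, ABCC2, AQP3, SLC39A10, SLC2A1 and DUSP6 (higher) and KNG1, HAMP, ACSS2 and FGA, the fibrinogen alpha chain (lower). Yijin and soshiho shared 226 higher and 191 lower calls, yijin and schisandra 214 and 209, and soshiho and schisandra 193 and 136. Independent lists of these sizes would share on average, in the pair with the most, 25.1 higher and 23.1 lower. These comparisons have no library in common. Over all tested genes the log2 changes correlated weakly across genes, with Pearson's r of 0.109, 0.0788 and 0.0400, and over genes of at least 8 CPM more, with 0.525, 0.492 and 0.454. For medium vs low dose over all tested genes r was -0.00245, -0.0755 and -0.0162. Genes are not independent replicates, so no p is given.

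**Figure D3:**
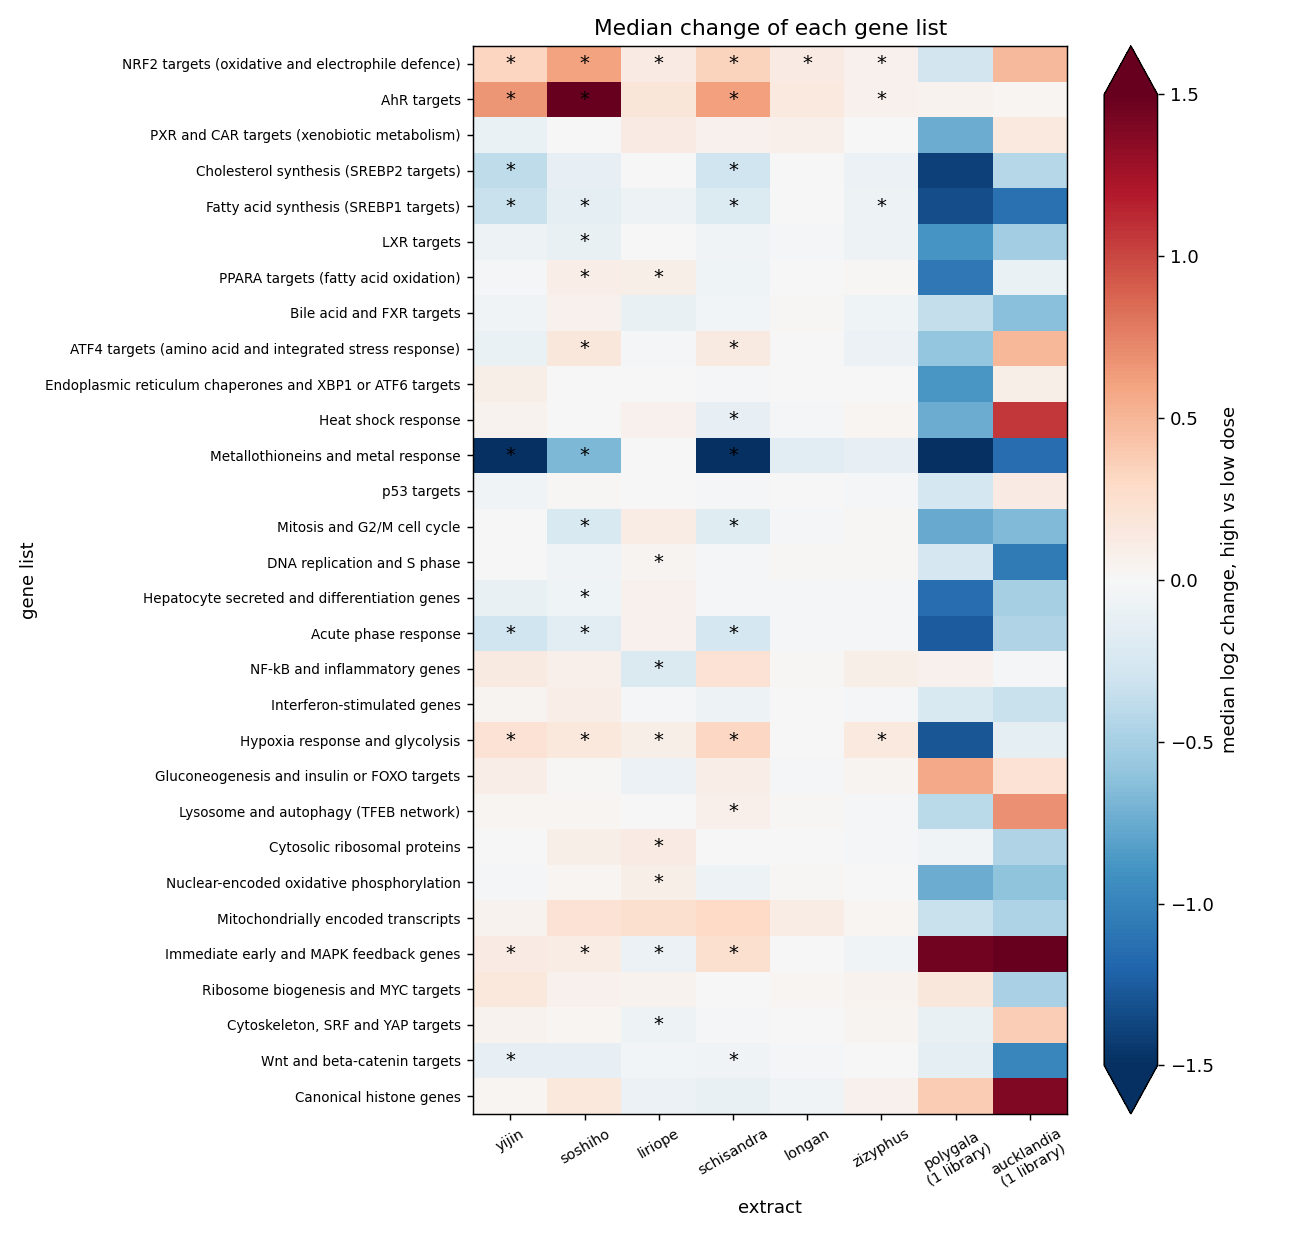
Median log2 change, high vs low dose, of the tested members of the 30 pathway lists (vertical) in each extract (horizontal), on a colour scale with 0 at white that ends at 1.5 either way; asterisks mark lists called in both comparisons. The metal response list was at -1.51 in yijin, -2.39 in schisandra and -0.67 in soshiho.

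Compared with vehicle, each dose of the 6 replicated extracts had over 1000 calls. Mitochondrially encoded transcripts made up 16.3 ± 1.85% of counts in the 3 vehicle libraries and 11.7, 11.5, 11.1 and 11.2% on average in the 4 treated code sets. MALAT1, a nuclear noncoding RNA, was at 267 CPM in vehicle and 423 to 548 CPM in the treated sets. The nuclease SLX1A was at 12.7 against 54.3 to 58.4 CPM, the ribosomal protein gene RPL39 at 85.5 against 132 to 142, and DUT, a dUTPase, at 25.4 against 34.6 to 42.7. TUBA1B-AS1, antisense to a tubulin gene, was at 87.3 CPM in vehicle and 1.90 to 5.58 CPM in the replicated sets, and 56.4 CPM in that of polygala and aucklandia. For some of these values single libraries of vehicle and treated sets overlapped. The mitochondrially encoded share reached 15.9% in the set of liriope and schisandra, against 15.2% in 2 vehicle libraries, and MALAT1 was as low as 233 CPM in that set, against 255 to 286 in vehicle. TUBA1B-AS1 ran from 32.8 to 157 CPM in vehicle and reached 26.8, 73.9 and 29.3 CPM in the replicated sets. In the set of polygala and aucklandia RPL39 was as low as 90.3 CPM and DUT 16.8 CPM, against at most 94.7 and 27.8 CPM in vehicle. These genes were chosen after their values were seen. SLX1A and RPL39 share sequence with close copies, so their reads could be split between copies. SLX1B, the copy of SLX1A, went the other way, at 45.7 CPM in vehicle against 14.0 to 22.4 CPM in the treated sets. Single libraries reached 44.9 CPM in the set of liriope and schisandra, against at least 40.4 CPM in vehicle. The SLX1A difference may thus lie in part in how reads were shared out between these copies. In all 6 replicated extracts 1200 genes differed at the low dose in the same direction, 489 higher and 711 lower. In 20 simulations of unchanged groups at most 0 did. All libraries were simulated there, vehicle included, independently around 1 mean per gene. A shift shared by the 3 vehicle libraries was thus not part of the simulations. Over the low doses, the mitochondrially encoded list was lower (median -0.78, adjusted p = 0.0333 with an estimated correlation), cytoskeleton genes lower (-0.13, 0.0426) and cholesterol synthesis higher (0.12, 0.0313). Oxidative phosphorylation (0.19) and heat shock genes (-0.12) passed only at the preset correlation (adjusted p = 0.366 and 0.127 with an estimated correlation), as did the list of cholangiocyte markers (-0.15, adjusted p = 0.127 with an estimated correlation). At the preset correlation alone hypoxia genes (0.17), PPARA targets (0.13), ribosomal proteins (0.10) and NRF2 targets (0.07) were also higher than in vehicle at the low doses. Wnt targets (-0.11), mitosis (-0.09), ribosome biogenesis (-0.09) and endoplasmic reticulum chaperones (-0.07) were lower. With an estimated correlation the adjusted p of these 8 lists was 0.105 to 0.848. Where an extract moved a list in its direction here, the high vs vehicle test of that list also contains this low-dose difference.

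At the high dose edgeR called 3953 genes against vehicle in yijin (1885 higher, 2068 lower), 3683 in soshiho (1796 and 1887), 2839 in liriope (1449 and 1390), 3733 in schisandra (1832 and 1901), 3321 in longan (1632 and 1689) and 2857 in zizyphus (1379 and 1478). The medium dose gave 2824, 1723, 3105, 3403, 3243 and 2822 in the same order, and the low dose 2578, 2019, 2807, 3646, 3405 and 2800. Both comparisons called 399 higher and 474 lower genes in yijin, 391 and 327 in soshiho and 333 and 308 in schisandra, with 6, 2 and 29 of opposite sign. Genes named for liriope, longan or zizyphus by their vehicle difference alone varied widely between replicates. EIF3CL, a close copy of EIF3C, was at 65.7 ± 86.5 CPM in vehicle and 8.10 ± 2.31 in high liriope. The noncoding 7SK was at 5.56 ± 2.05 and 1.14 ± 1.19, MT-ATP8 at 2032 ± 299 and 857 ± 293, ZACN at 2.60 ± 2.37 and 18.4 ± 10.4. In high longan CA9, a carbonic anhydrase, was at 10.5 ± 5.00 against 1.11 ± 0.477. RN7SL1 and RN7SL2, noncoding RNAs of the signal recognition particle, went from 22.0 ± 7.84 and 23.5 ± 10.2 CPM in vehicle to 7.02 ± 1.48 and 7.99 ± 1.95 in high longan. The EIF3CL call was lost without replicate 1 of vehicle (adjusted p = 0.568 in liriope, 0.331 in longan and 0.532 in zizyphus) and in liriope without replicate 1 of the high dose (0.0558), and that of RN7SL2 without replicate 3 of vehicle or 2 of longan (0.0745 and 0.0737). With library size alone as the scaling, the median of all genes moved to 0.0966 to 0.148 above vehicle, and the share of higher calls at the high dose was 79.9, 77.4, 84.9, 79.7, 88.4 and 88.0%, against 47.7, 48.8, 51.0, 49.1, 49.1 and 48.3% here. At the medium dose it was 86.2 to 91.1% against 46.5 to 48.9%, and at the low dose 87.6 to 91.5% against 45.9 to 48.9%.

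Single libraries moved some of these counts by more than 1.5 times. Without replicate 1 of vehicle the count was 1542 for low yijin, 1942 and 1757 for medium and low liriope, 2194 for medium schisandra. It was 2032, 2040 and 2242 for high, medium and low longan, 1872 and 1854 for high and low zizyphus, and 786 for the genes shared by the 6 low doses. It was 2014 and 2272 without replicate 2 or 3 of high soshiho, 595 and 613 without 2 or 3 of medium soshiho, and 895 and 612 without 2 or 3 of low soshiho. It was 1523 for low yijin without its replicate 3, and without their replicates 1 it was 1924 for medium longan, 2161 for low longan and 1710 for low zizyphus. When only the compared groups were fitted, high liriope gave 361 and low schisandra 504 calls.

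Polygala at its high dose of 250 µg/mL, 1 library per dose and so without a replicate check or a p-value, had CYP1A1 at 104 CPM against 9.67 at the low dose and 8.01 ± 0.390 in vehicle (n = 3). Other transcripts that were higher at each dose step included RASD1, a RAS-related dexamethasone-induced gene (5.69, 6.49 and 58.2 CPM), the growth factor AREG (5.21, 6.14 and 41.4 CPM) and the transcription factor SOX4 (26.0, 36.3 and 185 CPM). So were follistatin, FST (49.4, 55.3 and 259 CPM), TNFRSF12A (24.4, 28.7 and 126 CPM), the Notch ligand JAG1 (155, 178 and 572 CPM), CLCF1 (1.71, 1.78 and 15.2 CPM) and RELT (8.62, 10.3 and 40.5 CPM). Lower at each step were MAGED1 (424, 249 and 25.2 CPM), MAGED2 (82.7, 57.2 and 7.24 CPM), the matrix protein SPARC (135, 97.0 and 17.2 CPM) and gelsolin, GSN (259, 206 and 31.0 CPM), followed by vitronectin, VTN (114, 76.9 and 13.9 CPM), NUCB2 (25.0, 18.5 and 2.71 CPM) and EPRS1, a transfer RNA synthetase (173, 125 and 22.2 CPM). ALB was at 7461 and 3484, HMGCS1 at 445 and 114 and HMOX1 at 59.2 and 19.7 CPM at the low and high dose. ZACN, EIF3CL, MAGED4 and ATP6V1G2-DDX39B also met the rule, but their vehicle levels varied widely or they share reads with close copies or an overlapping gene.

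In polygala 389 genes were at least 2-fold higher and 1020 at least 2-fold lower at the high than at the low dose, of 9907 at 10 CPM or more, against 6 and 7 between medium and low. Same-number library pairs of the replicated extracts gave 0 to 49 such genes between high and low dose. Immediate early genes had a median log2 difference of 1.44 (percentile 100 among 10000 random lists matched on expression), with 16 of 21 at least 2-fold higher, and gluconeogenesis and FOXO targets 0.57 (99.9). Lower were cholesterol synthesis (-1.40, percentile 0, 17 of 24 at least 2-fold lower), fatty acid synthesis (-1.32, 0.01, 9 of 14), PPARA targets (-1.08, 0, 9 of 17), hepatocyte genes (-1.15, 0, 17 of 27), and acute phase genes (-1.24, 0, 11 of 15). So were hypoxia genes (-1.28, 0, 16 of 29), the metal response (-1.60, 0, 5 of 9), oxidative phosphorylation (-0.74, 0, 11 of 37) and mitosis (-0.76, 0.01, 10 of 28). PXR and CAR targets (-0.74, 0.48), LXR targets (-0.88, 0.37), ATF4 targets (-0.59, 0.34), endoplasmic reticulum chaperones (-0.87, 0.21) and the 5 immune cell markers (-0.85, 0.31) were lower too, and ribosomal proteins stayed at -0.06 (percentile 100). These percentiles are of high vs low dose. Against vehicle, PXR and CAR targets (percentile 1.59), ATF4 targets (3.94) and gluconeogenesis and FOXO targets (98.4) were not beyond percentile 1 or 99. The percentiles describe these libraries only.

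Aucklandia at 280 µg/mL, again with 1 library per dose, had the stress enzyme HMOX1 at 727 CPM against 84.7 at the medium dose, 56.9 at the low dose and 56.3 ± 3.77 in vehicle. IER3 was at 74.7, 95.2 and 745 CPM with rising dose and CCN1, a matricellular protein, at 13.5, 16.9 and 191 CPM. The small MAF factor MAFF was at 6.13, 8.03 and 135 CPM, adrenomedullin, ADM, at 5.84, 7.29 and 94.9 CPM, the growth factor HBEGF at 1.97, 2.24 and 43.7 CPM. The cytokine TNFSF9 was at 0.839, 1.28 and 31.1 CPM, PHLDA2 at 1.31, 2.82 and 34.5 CPM, KLF4 at 0.401, 0.497 and 16.5 CPM and EID3 at 0.255, 0.290 and 16.3 CPM. Lower at each step were SPTLC3, of sphingolipid synthesis (52.5, 46.3 and 1.94 CPM), the fatty acid binding protein FABP1 (81.4, 44.7 and 6.19 CPM), and DHRS2 (1993, 1536 and 180.0 CPM). So were the sodium channel SCN1A (30.3, 15.3 and 0.693 CPM), the amino acid transporter SLC6A14 (31.6, 17.9 and 0.739 CPM), UBD (17.0, 12.8 and 0.462 CPM), SORBS2 (35.5, 26.6 and 2.35 CPM) and HEPACAM (116, 113 and 9.93 CPM). SLX1B also met the rule but shares reads with its copy SLX1A. HMGCS1 was at 377 and 391, CYP1A1 at 9.56 and 18.8 and ALB at 7028 and 4955 CPM at the low and high dose.

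Of 10040 genes at 10 CPM or more in aucklandia, 980 were at least 2-fold higher and 1038 at least 2-fold lower at the high than at the low dose, against 8 and 4 between medium and low. Higher lists, all at percentile 100, were immediate early genes (median 1.99, 12 of 21 at least 2-fold higher), canonical histone genes (1.39, 7 of 13), heat shock genes (1.06, 10 of 18), and lysosome genes (0.69, 10 of 27). ATF4 targets (0.50, 10 of 28 higher and 5 lower) and NRF2 targets (0.49, 8 of 23 higher and 1 lower) were at percentile 100 too, and cytoskeleton genes (0.37) at 99.7. Lower were S phase genes (-1.05, percentile 0, 18 of 32 at least 2-fold lower), the metal response (-1.15, 0, 5 of 9), fatty acid synthesis (-1.12, 0.01, 7 of 14), Wnt targets (-0.98, 0.01, 6 of 13), mitosis (-0.66, 0.05, 5 of 28) and oxidative phosphorylation (-0.60, 0.04, 3 of 37). Against vehicle, oxidative phosphorylation (percentile 1.71) and cytoskeleton genes (98.6) were not beyond percentile 1 or 99. These single libraries cannot separate a response to the extract from a difference between libraries.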

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

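The 3 comparisons of extracts under the same dose and code set are all listed here, whatever their number of calls. Each was tested directly. Yijin and soshiho at the high dose differed in 598 genes, with CYP1A1 and SOS1 higher in soshiho. Liriope and schisandra differed in 1220 genes, with metallothioneins higher in liriope. Longan and zizyphus differed in 9 genes, among them ASNS and CYP1A1.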

How the results depend on the processing

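Of 187 named high vs vehicle results and 174 named high vs low results, 0 reversed under any alternative. RLE normalization kept all of them, and DESeq2 186 and 171. Library size alone as the scaling kept 173 and 170, and no filter 179 and 162. A fit of only the 2 compared groups, which estimates the spread from fewer libraries, kept 175 and 140. With an estimated correlation between genes 36 of 100 list calls against vehicle and 41 of 87 against the low dose were kept. Library size alone kept 80 and 83 of these list calls, and no filter 99 and 74. For other values that moved, the cause was not tested.

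With library size alone as the scaling the calls numbered 4659, 2627, 5198 and 4924 at the medium dose of yijin, soshiho, liriope and zizyphus. They numbered 4258, 3575, 4850, 5667 and 4584 at the low dose of yijin, soshiho, liriope, schisandra and zizyphus, and 2297 for the genes shared by the low doses. With only the compared groups they numbered, against vehicle, 361 for high and 1850 for low liriope, 504 for low schisandra, and 1618 for high and 1331 for low zizyphus. Between high and low dose this fit gave 1707 in soshiho, 0 in liriope, 132 in schisandra and 0 in zizyphus, and between extracts 1255 for yijin vs soshiho, 245 for liriope vs schisandra and 2 for longan vs zizyphus. Without the filter there were 207 calls between high and low liriope, 63 in longan, 79 in zizyphus and 106 for longan vs zizyphus. DESeq2 gave 14, 6 and 13 between high and low liriope, longan and zizyphus. Of the alternatives chosen after seeing the data, those for gene counts were the length and GC correction, with 8 calls in liriope and 17 in zizyphus, and leaving out the 2 outlying libraries, with 731 in schisandra and 15 in zizyphus. The median correlation between extracts over 15 pairs was 0.216 with genes of a mean log2 CPM of at least 3. Over all tested genes r of the pairs ran from -0.0369 to 0.109, and for medium vs low dose from -0.0805 to 0.0652.

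Without the 2 outlying libraries 6 list results turned direction. In liriope these were ribosomal proteins against vehicle (adjusted p = 0.890) and against the low dose (0.458), endoplasmic reticulum chaperones (0.0476), hepatocyte genes (0.0577) and mitochondrially encoded transcripts (0.967) against the low dose. In schisandra they were ribosomal proteins against the low dose (0.019).

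Leaving out 1 library at a time, the calls ranged as follows. For high, medium and low dose against vehicle and high against low they were 3130 to 3413, 1970 to 2360, 1523 to 2308 and 836 to 1039 in yijin. In soshiho they were 2014 to 3239, 595 to 1449, 612 to 1675 and 467 to 501. In liriope they were 2013 to 3186, 1942 to 2845, 1757 to 2496 and 2 to 6. In schisandra they were 2681 to 3327, 2194 to 3004, 2446 to 3826 and 615 to 1826. In longan they were 2032 to 2992, 1924 to 2894, 2161 to 3028 and 0 to 2. In zizyphus they were 1872 to 2689, 1996 to 2446, 1710 to 2590 and 3 to 7. Yijin vs soshiho ranged from 267 to 469, liriope vs schisandra from 805 to 1205, longan vs zizyphus from 4 to 10, and the shared low-dose genes from 786 to 1046.

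A block for the replicate number gave 1398 calls between high and low yijin, 903 in soshiho and 1337 in schisandra, and moved only liriope by more than 1.5 times, to 8. With the block 3 soshiho lists did not pass against vehicle: immediate early genes (adjusted p = 0.0761), LXR targets (0.0524) and hepatocyte genes (0.0508). The numbers were not taken as pairs, since only 142 of 360 same-number pairs had a correlation over 0.1. The median was 0.044, against -0.019 for other pairs, and 30 of 48 libraries correlated best with their own number, a hint of shared structure. The 360 pairs were pooled over code sets, and the block gave a number the same effect in every set. Pairing within a code set was therefore not tested. With 0.5 or 5 CPM added in place of 1 CPM, 1471 or 1043 polygala genes and 2083 or 1489 aucklandia genes were at least 2-fold apart between high and low dose, against 1409 and 2018. At 5 CPM, 36 of 47 named values and 47 of 68 list medians moved by at least their SD over the vehicle libraries. At 0.5 CPM 16 and 19 did.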

Other observations

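Values of 3 zinc transporter genes are given here without a test of them as a group. SLC39A4, a zinc importer chosen after its values were seen, rose between low and high dose from 93.9 to 133 CPM in yijin (log2 0.50 ± 0.057, adjusted p = 1.8e-08). It rose from 99.6 to 129 CPM in soshiho (0.36 ± 0.070, adjusted p = 3.7e-04) and from 86.9 to 155 CPM in schisandra (0.84 ± 0.057, adjusted p = 1.0e-14). SLC39A10, another importer, rose by 0.96 ± 0.082, 0.65 ± 0.10 and 0.95 ± 0.081, and the exporter SLC30A1 changed by -0.36, -0.28 and -0.77, the soshiho call being lost without any 1 of its 4 libraries. Against vehicle SLC30A1 in soshiho was at -0.16 (adjusted p = 0.0917) and did not pass. In liriope, longan and zizyphus SLC39A4 was at 0.04, 0.02 and 0.10 and did not pass.

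The 2 libraries farthest from their replicates were replicate 1 of low schisandra and replicate 2 of high liriope, with totals of 38.0 and 37.6 M counts and SDs of log2 differences of 0.243 and 0.215.

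The library set test of the vehicle difference and the SOS1-IT1 test were chosen only after the result was seen. The 3 vehicle libraries stood apart from every treated group of the 6 replicated extracts. Polygala and aucklandia were not tested. A smooth trend with annotated length or GC does not account for most of the vehicle difference. After that correction 94.8% of the 1200 shared genes were still called, and 1531 genes were shared in all. Length or GC effects of another form were not tested. Over the 1200 genes the high-dose difference was 0.968 times the low-dose one (0.895 to 1.00 over 6 extracts). The genes were chosen by their low-dose calls, and both differences share the vehicle libraries. The ratio therefore cannot exclude a response that grows with dose. A library set difference and a response already full at the low dose cannot be told apart, since 0 of 57 treated libraries are in the set of the vehicle.

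The fall of metallothioneins could come from short transcripts, but the 2214 other genes no longer than 704 nt had a median of -0.012 in schisandra and 0.013 in yijin, against -2.59 and -1.58 for 7 metallothioneins. It could come from replicate 1 of low schisandra, but without it the median was -1.997 and all 7 were still called. Less metal-responsive transcription is a hypothesis of this text. It predicted a fall of the zinc exporter SLC30A1, which is driven by the same factor, and in yijin this changed by -0.36 ± 0.060 (adjusted p = 3.5e-05). SLC30A1 is itself a member of the metal response list and was counted among its lowered genes. This outcome was therefore not separate from the fall of that list. Zinc itself was not measured.

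The rise of SOS1 in soshiho may reflect its neighbourhood, but 8 other genes within 500 kb had a median of 0.044, from -0.08 to 2.36. The highest was CDKL4, named after its values were seen, at 2.36 (adjusted p = 0.0049). It lies at 39175646 to 39229588 on the same strand as SOS1, with low levels of 0.270 and 1.40 CPM at low and high dose. The median cannot exclude a rise shared by SOS1 and CDKL4 alone. A single library is excluded, with 2.13 to 2.16 in the leave-one-out fits. Intron reads and a rise of the mature transcript cannot be told apart, since the fold of SOS1-IT1 was 0.802 times that of SOS1 (0.671 to 0.958). In yijin SOS1 changed by 0.30 (adjusted p = 0.0010) between low and high dose, and the high dose was at -0.02 against vehicle (adjusted p = 0.862), which did not pass.

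Regrouping 6 libraries gives 10 splits, so no share under 0.05 can come of it. A rank here is the number of splits, the real one included, with at least as many calls as the real grouping. The real grouping ranked 1 of 10 in all vehicle comparisons, given here for the high, medium and low dose with the highest other split in brackets. It had 4176 (0), 2632 (0) and 2246 (1) calls in yijin and 361 (2), 3056 (0) and 1850 (1) in liriope. It had 3574 (0), 2741 (0) and 504 (0) in schisandra, 3225 (0), 2779 (0) and 3353 (0) in longan, and 1618 (1), 2563 (0) and 1331 (0) in zizyphus. Between high and low dose it ranked 1 in yijin, with 1893 (1), and in schisandra, with 132 (0). It ranked 3 in longan, with 2 (3). It ranked 10 in liriope, with 0 (3), and in zizyphus, with 0 (302), a rank fixed because every split has at least 0 calls. In all of these another grouping of the samples has more calls. The real grouping ranked 1 for liriope vs schisandra, with 245 (0), and 2 for longan vs zizyphus, with 2 (4).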
